A study of Mus musculus with 3 samples.

How the data were processed

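Mouse bone marrow was profiled by droplet 3' single-cell RNA sequencing (10x Genomics version 3.1) in 3 libraries, 2 labelled with the Ep300-Znf384-V5-HA genotype (fusion knock-in) and 1 labelled wild type. Per the labels' protocols, all came from males aged 6 weeks, and each library pooled 5000 sorted live marrow cells with 5000 live lineage-negative cells after red cell lysis. The deposited values were raw UMI counts per gene and cell barcode. Per the submitters' processing notes, these counts were made with bcl2fastq 2.20.0.422 and Cell Ranger 5.0.1 on GRCm38, while the matrix headers name Cell Ranger 5.0.0. No barcode held fewer than 500 UMIs in any library. The files list 32285 genes, of which 32158 had a position in GENCODE M21 (GRCm38), and 0 features named for the fusion or its tags. No sequencing batch is given.

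Barcodes with at least 1000 UMIs, at least 400 genes and at most 10% mitochondrial UMIs were kept, and predicted doublets were removed per library with the scrublet method in scanpy 1.11.5 (expected rate 0.06). In fusion replicate 1, wild type and fusion replicate 2, 225, 194 and 318 barcodes were removed as doublets. The cells of the 3 libraries were clustered together, without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). The clustering gave 29 clusters. Clusters were named by the best-scoring marker list, with at least 3 of its genes detected in 10% of the cells, and joined into 14 classes with 0 unnamed cells, so a class name stands for cells resembling that type by markers. The joined marker lists for pre-B to mature B cells and for T and NK cells were made after some clusters that mixed these types had stayed unnamed. Every class held at least 50 cells in every library. The megakaryocyte-erythroid progenitor and early erythroid class is called erythroid progenitors, and the basophil and mast cell class basophils.

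UMI counts were summed per library and class. Genes kept by filterByExpr were tested with the edgeR 4.0.16 quasi-likelihood test (TMM normalization, genotype as the only term), with Benjamini-Hochberg adjusted p under 0.05 over the genes of a class. Log2 fold changes are fusion over wild type with standard errors (SE). CPM values of genes tested are on TMM effective library sizes, and those of the targeted genes are plain CPM. With 2 libraries against 1, the fit had 1 residual degree of freedom, from the fusion libraries, and the wild-type library was assumed to vary like them. The labels do not say whether the libraries come from separate animals, so the p-values measure spread between samples, which may be technical, and genotype cannot be separated from the single wild-type library. The classes come from the same 3 libraries and are not independent of each other. Of 35 gene lists, 34 had at least 5 tested members in a class and were tested with camera of limma 3.58.1 (log2 CPM with prior count 2, preset correlation 0.01), adjusted over 405 list and class pairs. With an estimated correlation, the smallest adjusted p over all pairs was 0.814, so no list call held. That version estimates the correlation from 1 residual degree of freedom and could hardly pass, so it decides little. The list calls rest on the preset correlation alone.

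Class shares are of all kept cells, with exact Clopper-Pearson 95% intervals, which cover counting error only. A share was described as higher or lower where the intervals of both fusion libraries lay on the same side of the wild-type interval. The two-sided exact permutation test over the 3 labellings cannot go below p = 0.333. For 1 progenitor question, the share of cells with a UMI of both a granule and an early B cell gene was taken after thinning each cell to 2000 UMIs, with T, NK and innate lymphoid cells as background. Folds against 0 counts are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of plain CPM is given with its exact 95% counting interval.

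The tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Under the naming rule, genes had a mean CPM of at least 20, both fusion libraries on one side and at least 5% of the highest class CPM of the gene. The named genes were taken from the first 10 per direction by absolute log2 fold change in stem and multipotent progenitors and the first 5 elsewhere. Free places went to genes described by size and not called: both fusion libraries at least 1 from the wild type on the log2 scale, and at least 3 times the difference between them. Predicted, immunoglobulin, T cell receptor, haemoglobin, ribosomal, mitochondrial, Xist and Y-linked genes were not named under the rule, and up to 4 members of each described list were added. One gene that the rule gave in mature neutrophils is not reported here. Chosen after seeing the data were 10 alternatives: clustering without the called genes, shares outside the erythroid classes, stem with lymphoid progenitors as a single class, monocytes without dendritic cells, the larger monocyte cluster without dendritic cells, plasmacytoid dendritic cells named at both resolutions 1 and 2, granulocyte-monocyte progenitors named at both, mature neutrophils of the clustering without called genes, the larger basophil cluster, and the immature neutrophil clusters shared by all libraries. The requirement that a list compared between classes hold at least 1 called member per direction was also set after the lists had been seen.

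The alternatives chosen beforehand were Leiden resolutions 0.5 and 2, classes carried over from a clustering of the wild-type library, doublets kept, a filter of at least 2000 UMIs, 800 genes and at most 5% mitochondrial UMIs, shares within a compartment and an edgeR test of class counts. For genes and lists they were DESeq2 1.42.0, DESeq2 size factors in edgeR, no gene filter, equal cells per library, leaving out each fusion library, an estimated correlation, and fry. The gene test was tested on simulated counts with 200 genes changed per class. Of genes changed 2-fold, it recovered 41.8% in stem and multipotent progenitors, 79.6% in granulocyte-monocyte progenitors, 62.2% in erythroid progenitors, 50.0% in mature neutrophils and 9.68% in pro-B cells. For genes changed 4-fold, the values were 85.7%, 97.0%, 88.7%, 87.0% and 84.2%, with 2, 8, 6, 12 and 1 false calls per class. The simulation used the trended dispersion for every gene and let the wild-type library vary like the fusion libraries. Its values hold under these assumptions and do not measure the power or error rate on the real counts. Further tools were Python 3.11.15, R 4.3.3, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.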

Results

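The study asks, by its title, how ZNF384 fusion proteins alter blood lineages, and the files hold the bone marrow transcriptome of 2 fusion knock-in libraries and 1 wild-type library at single-cell level. Fusion replicate 1, wild type and fusion replicate 2 held 9057, 9354 and 8122 barcodes and 97192347, 93262028 and 111836603 UMIs. After filtering, 7313, 7431 and 6895 cells were kept, with a median of 7360, 7430 and 10008 UMIs per cell. The 21639 cells fell into 14 classes, from stem and multipotent progenitors to mature neutrophils, B cells and erythroblasts.

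The targeted genes moved in opposite directions. Over all cells, Ep300 (ENSMUSG00000055024, chromosome 15, 81585351 to 81652077), the histone acetyltransferase gene that gives the fusion its first part, was lower in fusion, at 69.2 and 52.95 plain CPM against 85.8 in wild type. Zfp384 (ENSMUSG00000038346, chromosome 6, 125009145 to 125037870), the mouse gene for ZNF384, was higher, at 26.5 and 19.5 CPM against 15.6. In the edgeR quasi-likelihood fit over all cells, Ep300 changed by −0.49 ± 0.16 on the log2 scale (Benjamini-Hochberg adjusted p = 0.0369) and Zfp384 by 0.57 ± 0.16 (adjusted p = 0.0206). Both fusion libraries were below wild type for Ep300 in 13 of 14 classes, of which 2 were called, and above it for Zfp384 in 12 of 14, of which 1 was called. The called Zfp384 class was mature neutrophils (log2 fold change 1.28 ± 0.28, edgeR adjusted p = 0.00139). The 3' end of the fusion allele is not given in the sources used here, so tags could not be assigned to the fusion or the normal transcript.

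The shares of erythroid progenitors and megakaryocytes were higher in the fusion libraries. Erythroid progenitors made up 29.9% and 31.0% of fusion cells (30.5% ± 0.77, SD, n = 2) against 13.97% of wild-type cells, with Clopper-Pearson intervals of 28.9 to 31.0%, 29.9 to 32.1% and 13.2 to 14.8%. Megakaryocytes made up 1.78% and 1.64% against 0.929%, and mature neutrophils 26.3% and 21.4% against 17.7%, though the mature neutrophil ratio fell from 1.35 to 1.01 at Leiden resolutions 0.5 and 2, where immature neutrophils were higher (1.46 and 1.49). Stem and multipotent progenitors held 2.98% and 3.19% against 1.99%, a fusion to wild type ratio of 1.55 as classified. The ratio stayed at 1.63 at Leiden resolution 2 and 1.55 with the stricter filter. The direction turned in other settings: 0.620 at Leiden resolution 0.5 and 0.542 with classes from the wild-type library. It was 0.966 with doublets kept and 0.639 when clustered without called genes.

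Lymphoid cells made up a smaller share of the fusion libraries. Lymphoid progenitors, which express Dntt and Flt3, made up 1.29% and 1.39% of fusion cells (intervals 1.04 to 1.57% and 1.13 to 1.70%) against 5.19% (4.70 to 5.72%) in wild type. Stem, multipotent and lymphoid progenitors together made up 4.27% and 4.58% against 7.19%, a ratio of 0.616 that came to 0.966 with doublets kept. Pro-B cells held 0.752% and 1.07% against 2.03%, pre-B to mature B cells 2.28% and 2.29% against 4.79%, and T, NK and innate lymphoid cells 1.35% and 1.07% against 2.95%. The share of basophils was lower as well, at 2.61% and 3.90% against 8.10%, and that of plasmacytoid dendritic cells was at 1.87% and 2.25% against 3.89%. Granulocyte-monocyte progenitors were at 8.41% and 10.7% against 16.1%, and monocytes at 3.42% and 3.92% against 5.56%. In all, 4 classes were higher, 8 lower and 2 not apart from wild type: erythroblasts (1.26% and 1.90% against 1.10%, but higher with wild-type classes, with doublets kept and when clustered without called genes) and immature neutrophils (15.8% and 14.3% against 15.7%). The exact permutation test gave p = 0.333 for the classes described as higher or lower except mature neutrophils (p = 0.667), p = 0.667 for erythroblasts and p = 1 for immature neutrophils, and 0.333 is the smallest the 3 labellings allow. An edgeR quasi-likelihood test of class counts passed 8 classes, among them lymphoid progenitors (ratio 0.258, adjusted p = 0.0115) and erythroid progenitors (2.18, adjusted p = 0.0254).

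**Figure D1:**
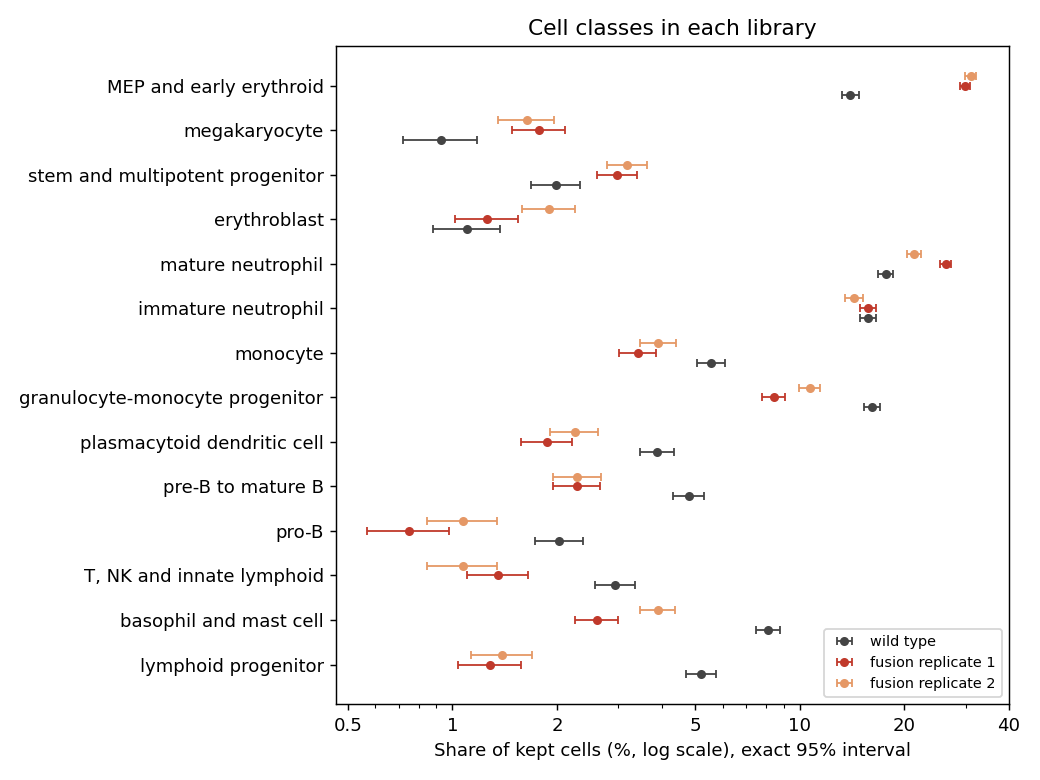
Share of all kept cells in each of the 14 classes, in percent on a log scale, with 1 point per library (wild type and both fusion replicates) and exact 95% intervals for counting error as error bars. Erythroid progenitors stand at 29.9% and 31.0% in fusion against 13.97% in wild type, and lymphoid progenitors at 1.29% and 1.39% against 5.19%.

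Within classes, 2002 genes passed edgeR in at least 1 of 13 classes. Mature neutrophils (319 higher and 476 lower), basophils (198 and 526) and immature neutrophils (214 and 441) held the most called genes by edgeR with all cells, an order that did not hold under every alternative: basophils had 0 with equal cells (1185 at an unadjusted p under 0.05), and DESeq2 called 243 in mature neutrophils, 121 in immature neutrophils, 83 in erythroid progenitors and 49 in basophils. In the sum of all cells, which mixes class shares with expression, 612 genes were higher and 1828 lower.

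Single genes typical of several lineages changed in stem and multipotent progenitors of the fusion marrow. Il10ra (the interleukin-10 receptor gene, ENSMUSG00000032089), Apoe (apolipoprotein E, a lipid carrier, ENSMUSG00000002985), Cpa3 (a mast cell carboxypeptidase), Deptor (an mTOR inhibitor) and Ctsg (the granule protease cathepsin G) rose. Ly6a (the stem cell antigen Sca-1), Mecom (a stem cell transcription factor), Dntt (which adds bases at antigen receptor joints), Klf2, Ifitm1 and Ms4a6c fell. Il10ra reached 43.7 and 33.1 CPM against 6.03 in wild type (log2 fold change 2.65 ± 0.38, edgeR adjusted p = 0.00349) and Apoe 392.2 and 334.0 against 111.0 (1.71 ± 0.22, adjusted p = 0.00157). Dntt stood at 38.2 and 47.7 CPM against 106 (−1.30 ± 0.20, adjusted p = 0.00576), Ly6a at 13.7 and 31.2 against 82.0 (−1.84 ± 0.30, adjusted p = 0.00857) and Mecom at 23.1 and 21.4 against 51.9 (−1.22 ± 0.22, adjusted p = 0.0252). Of 10433 genes tested, 6 were higher and 35 lower by edgeR. With wild-type classes, where no separate lymphoid progenitor class formed, 406 were called. Without the gene filter 116 were called, with equal cells 18 and by DESeq2 7. The changes in this class are not separated from where its border with lymphoid progenitors was drawn. Dntt and Ms4a6c reached at most 6.50% and 6.49% of their highest class CPM, so their falls are not separated from free RNA either. Ly6a and Shisa8 (log2 fold change −1.63 ± 0.27, edgeR adjusted p = 0.0127) lie 6.59 and 0.621 Mb from Ep300. Trim47, Dok2 and Psd3 were higher, described by size and not called.

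As sets in these progenitors, the lymphoid priming list was lower and the erythroid list higher. The lymphoid priming list (median log2 fold change −0.43, 1 of 10 members lower over all genes and 3 adjusted over the list alone) passed camera (adjusted p = 0.0058) and gave adjusted p = 0.814 with an estimated correlation. The fall of this list is not separated from where the border with lymphoid progenitors was drawn. The erythroid list, with Hbb-bt, Car1 and Gata1 in front by size, had a median of 0.40, with 0 of 18 members called over all genes by edgeR and 3 adjusted over the list alone, and camera adjusted p = 0.00239 (adjusted p = 0.814 with an estimated correlation). Its median was also 0.46 in the shared immature neutrophil clusters and 0.25 in mature neutrophils clustered without called genes. In monocytes without dendritic cells it was 0.20 (0.03 in the larger cluster), and in plasmacytoid dendritic cells named at both resolutions −0.01. The rise of the erythroid list in stem and multipotent progenitors is therefore not separated from free RNA. The stem cell self-renewal list had 2 of 22 members lower (Ifitm1 and Mecom), 4 adjusted over the list alone, and did not pass camera (median −0.30, adjusted p = 0.0978).

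Lymphoid progenitors shared the rise of Apoe, and Bcl11b, a transcription factor of T cell commitment, rose with it. Hmga2 (a chromatin protein), Fosb and Tmem108 fell, as did Ly6a. Apoe stood at 60.8 and 39.8 CPM against 3.42 in wild type (log2 fold change 3.83 ± 0.39, edgeR adjusted p = 0.00142) and Bcl11b at 96.8 and 90.1 against 32.2 (1.53 ± 0.23, adjusted p = 0.0177). By edgeR, 7 genes were higher and 9 lower, while 45 were called with DESeq2 size factors, 113 without the gene filter, and 6 each by DESeq2 and with equal cells. The T and NK cell list was higher (median 0.90, camera adjusted p = 3.32e-05), with Trbc1, Tcf7 and Thy1 higher and Klrd1 lower by size, 0 of 11 members called over all genes by edgeR and 5 higher and 1 lower adjusted over the list alone. This list gave adjusted p = 0.814 with an estimated correlation.

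In granulocyte-monocyte progenitors, edgeR called 0 of 12151 genes, with 865 at an unadjusted p under 0.05, and DESeq2 called 36. By size and not called, Apoe was higher (79.8 and 74.6 CPM against 21.1, edgeR adjusted p = 0.0886), and Ccnd1 (cyclin D1), Ccr2 (a monocyte chemokine receptor), Mpeg1 and Klf4 were lower, by −1.96, −1.89, −1.67 and −1.64 on the log2 scale. The monocyte and macrophage list was lower (median −0.53, 10 of 17 members adjusted over the list alone, camera adjusted p = 9.23e-10, adjusted p = 0.814 with an estimated correlation). The immediate early gene list was lower as well, with Fosb, Klf4, Atf3 and Fos in front (median −0.63, 9 of 18 adjusted over the list alone, camera adjusted p = 3.21e-07, adjusted p = 0.814 with an estimated correlation). The class mixes clusters: the cluster nearest to monocytes held 152 and 221 fusion cells and 425 of wild type. Among the cells that kept their name at resolution 2, edgeR called 5 genes, Apoe, Ccnd1 and Mpeg1 among them, and 1 of 16 monocyte and macrophage members (median −0.44) and 0 of 18 immediate early genes (median −0.54) were lower.

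Erythroid progenitors of the fusion marrow had more Nrgn (neurogranin), Tspan8 (a tetraspanin) and Alad (a heme synthesis enzyme) and less Mt2 (metallothionein), Lgals1 (galectin-1) and Plac8. Nrgn stood at 127 and 131 CPM against 46.0 (log2 fold change 1.49 ± 0.15, edgeR adjusted p = 0.00202), Alad at 336 and 318 against 178 (0.88 ± 0.18, adjusted p = 0.0487) and Lgals1, 2.66 Mb from Ep300, at 65.4 and 79.3 against 177 (−1.29 ± 0.15, adjusted p = 0.00328). By edgeR, 40 genes were higher and 126 lower, but 0 were called without the gene filter (934 at an unadjusted p under 0.05) and 30 with wild-type classes, and DESeq2 called 83. Monocyte genes such as Fn1, Ccr2, F13a1 and Cx3cr1 were lower at low levels, under 3 CPM in wild type: 7 of 17 list members were lower over all genes and 14 adjusted over the list alone (median −1.34, camera adjusted p = 9.18e-14, adjusted p = 0.814 with an estimated correlation). The same list was lower in T, NK and innate lymphoid cells, used as the measure of free RNA (median −1.58).

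In erythroblasts, Tcf7l2 (a Wnt pathway factor, log2 fold change 3.09 ± 0.34, edgeR adjusted p = 0.00125), H1f0 (a linker histone, 2.56 Mb from Ep300) and Fabp5 rose, and Mt2, Sp100 and Alas2 (the erythroid enzyme that starts heme synthesis) fell, with 6 genes higher and 30 lower. Megakaryocytes had lower Gp1ba (the platelet receptor for von Willebrand factor), Tesc, Tpm4, Gnaz and Plac8, with 0 genes higher and 6 lower by edgeR, though 62 were called with DESeq2 size factors, 102 with equal cells, 147 without the gene filter and 1 by DESeq2. Gp1ba stood at 26.9 and 25.5 CPM against 93.2 (log2 fold change −1.83 ± 0.20, edgeR adjusted p = 0.049). The megakaryocyte list was lower there, with Gp6, Selp and Ppbp next by size (median −0.33, 6 of 21 members adjusted over the list alone, camera adjusted p = 8.14e-05, adjusted p = 0.814 with an estimated correlation). All 33 tested G2 and M phase genes were higher in megakaryocytes, with 0 called by edgeR over all genes or adjusted over the list alone (median 0.53, camera adjusted p = 8.31e-09, adjusted p = 0.814 with an estimated correlation).

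In the clustering used, neutrophils separated by genotype, but without the called genes the 2 mature clusters mixed the libraries (696 and 587 fusion cells with 567 of wild type, and 1332 and 963 with 954). With these genes, mature neutrophils formed 4 clusters, of which 3 held 838, 791 and 287 cells of fusion replicate 1, 681, 607 and 175 of fusion replicate 2 and 5, 1 and 0 of wild type, while the other held 1309 wild-type cells and 7 and 10 fusion cells. Mature neutrophils of the fusion marrow expressed Ptger3 (a prostaglandin E2 receptor, ENSMUSG00000040016), Grap (a signalling adaptor, ENSMUSG00000004837), Clmp (an adhesion molecule), Abcc3 (a transporter) and Ldhc (a lactate dehydrogenase typical of testis). They had little Wfdc17 (ENSMUSG00000069792), Steap4 (a metalloreductase), Klra17 and Il1rn (the interleukin-1 receptor antagonist). Ptger3 had 530 counts in fusion and 0 in wild type and was at least 67.8-fold higher. Grap had 3487 counts against 3, a 446-fold ratio (counting interval 153 to 2166), Clmp 354 against 1 (136-fold, 24.2 to 5385) and Abcc3 463 against 3 (59.3-fold, 20.2 to 288). Ldhc stood at 139 and 110 CPM against 2.81 (log2 fold change 5.46 ± 0.35, edgeR adjusted p = 8.21e-14), Wfdc17 at 12.1 and 18.5 against 588 (−5.27 ± 0.23, adjusted p = 4.55e-18) and Il1rn at 14.5 and 17.2 against 171 (−3.43 ± 0.21, adjusted p = 2.75e-14).

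Granule transcripts of mature neutrophils changed, in part with where the class was drawn. Camp (cathelicidin), Ltf (lactoferrin), Chil3 and Mmp8 (a collagenase), which fill the later granules, rose, and Mpo (myeloperoxidase), Ms4a3, Prtn3 (proteinase 3) and Serpinb1a of the primary granule list fell. Ltf stood at 2024 and 2395 CPM against 516 (log2 fold change 2.10 ± 0.25, edgeR adjusted p = 1.25e-07) and Mpo at 72.9 and 44.4 against 246 (−2.06 ± 0.21, adjusted p = 5.92e-09). The secondary and tertiary granule list had 7 of 18 members higher and 1 lower (8 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.000752). The primary granule list had 7 of 13 lower (8 adjusted over the list alone, median −1.17, camera adjusted p = 0.000118). Both lists gave adjusted p = 0.814 with an estimated correlation, and a difference between them was not tested. The class is drawn differently by genotype: a cluster of 836 wild-type cells, named immature here, went in part to the mature class at resolutions 0.5 and 2. In the mature neutrophils of the clustering without called genes, edgeR called 660 genes, 4 of 18 late granule members were higher and 1 lower (median 0.12), Ltf was not called (0.56 ± 0.23, adjusted p = 0.198), and 7 of 13 primary granule members were lower (median −1.06). Mpo also fell in T, NK and innate lymphoid cells, the measure of free RNA (29.95 and 34.05 against 123 CPM), so its fall in mature neutrophils is not separated from free RNA.

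**Figure D2:**
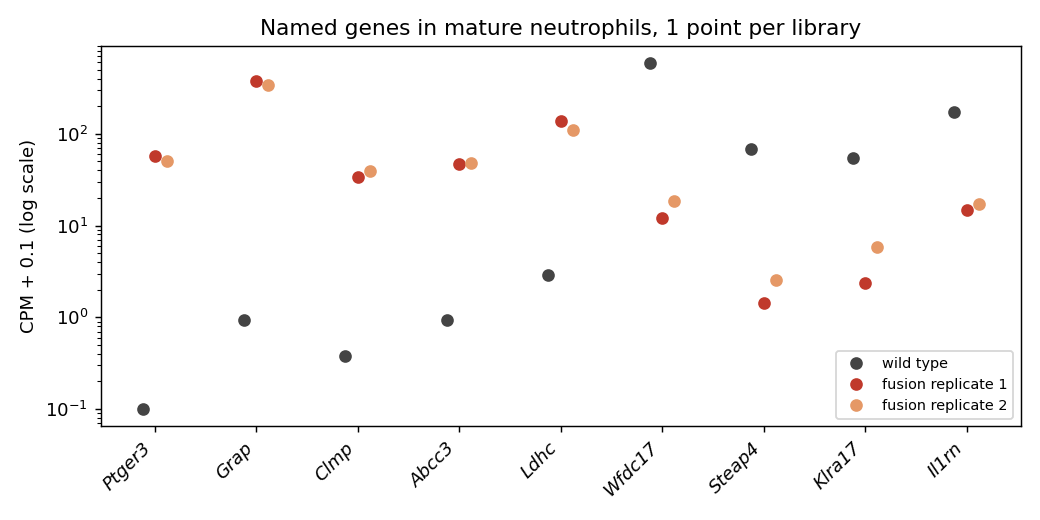
CPM + 0.1 on a log scale (TMM effective library sizes) of the genes named above in mature neutrophils, with 1 point per library. Grap lies at 374 and 336 CPM in the fusion libraries and 0.842 in wild type, and Wfdc17 at 12.1 and 18.5 against 588.

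Immature neutrophils repeated part of this picture: Grap, Ces1d (a carboxylesterase), Mcam (CD146), Spp1 (osteopontin) and Ldhc rose, and Ccr1 (a chemokine receptor), S100a6, Thbs1 (thrombospondin), Clec4e and Cmah fell. Spp1 stood at 90.4 and 75.7 CPM against 7.53 (log2 fold change 3.46 ± 0.22, edgeR adjusted p = 4.12e-12) and Ccr1 at 8.18 and 10.8 against 130 (−3.78 ± 0.18, adjusted p = 1.79e-14). Endoplasmic reticulum chaperones such as Hspa5 (1.18 ± 0.19, edgeR adjusted p = 6.82e-05), Creld2 and Pdia6 were higher and Asns lower, with 6 of 19 unfolded protein response genes higher and 1 lower (11 and 1 adjusted over the list alone, median 0.42, camera adjusted p = 3.2e-05, adjusted p = 0.814 with an estimated correlation). One of the 4 immature clusters held 650 and 544 fusion cells and 5 wild-type cells, and another 836 wild-type cells and 7 and 25 fusion cells. In the 2 clusters that all libraries shared, edgeR called 108 genes against 655 in the whole class, Grap (5.38 ± 0.46, adjusted p = 0.000194) and Spp1 (3.60 ± 0.23, adjusted p = 4e-05) among them, and 1 of 19 unfolded protein response genes was higher and 1 lower (median 0.28). Clec4e (−1.33 ± 0.41, edgeR adjusted p = 0.208) and Cmah (−1.40 ± 0.31, adjusted p = 0.0651) were not called there.

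Monocytes of the fusion marrow had more transcript of antigen presentation genes and Spp1 (ENSMUSG00000029304) and less of several monocyte genes. Ciita (the transactivator of MHC class II genes, ENSMUSG00000022504), H2-Aa, H2-Eb1, Cd74 (the invariant chain), Pltp and Bank1 rose, and Vcan (versican), Fn1 (fibronectin), Ccr1, Fcnb and Msr1 (a scavenger receptor) fell. Ciita stood at 47.4 and 39.5 CPM against 5.83 (log2 fold change 2.88 ± 0.30, edgeR adjusted p = 1.61e-05) and Vcan at 13.9 and 4.89 against 198 (−4.46 ± 0.30, adjusted p = 4.34e-08). By edgeR, 54 genes were higher and 107 lower, while 39 were called with wild-type classes, 36 by DESeq2 and 295 without the gene filter. The MHC class II list had 6 of 11 members higher (7 adjusted over the list alone, median 2.0, camera adjusted p = 4.04e-08, adjusted p = 0.814 with an estimated correlation). Dendritic cells made up 11.2% and 7.04% of the class in fusion and 2.42% in wild type. Without them, 5 of 11 MHC class II genes were still higher, with H2-Aa at 3.94 ± 0.28 and Ciita at 2.86 ± 0.50 on the log2 scale (edgeR adjusted p = 6.21e-10 and 0.00101). A smaller cluster led by Clec4a3, Ace and Cx3cr1 made up 18% and 27.0% of the class in fusion and 11.4% in wild type. In the larger cluster alone and without dendritic cells, edgeR called 189 genes, 5 of 10 MHC class II genes were higher, and Vcan (−4.42 ± 0.30, adjusted p = 9.3e-11) and Fn1 (−2.93 ± 0.27, adjusted p = 3.84e-08) were lower, but Pltp was not called (0.53 ± 0.84, adjusted p = 0.934). Within the monocyte and macrophage list, Fn1, Fcgr1 (an Fc receptor), Mpeg1 and Klf4 fell (4 of 18 lower, 5 lower and 1 higher adjusted over the list alone, median −0.45, camera adjusted p = 0.00139, adjusted p = 0.814 with an estimated correlation).

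The plasmacytoid dendritic cell class had more Neurl3, Grap, St6gal1, Spp1 and Zbtb20 and less Klk1, Atf3, Ccl9, Prkca and Fosb, with 29 genes higher and 72 lower by edgeR. At Leiden resolution 2, 28 of its 137 and 46 of its 155 fusion cells and 96 of its 289 wild-type cells were still named plasmacytoid dendritic cells, so the class mixes types. Among these, edgeR called 23 genes, Grap (2.11 ± 0.41, adjusted p = 0.000254), Zbtb20, Klk1 and Prkca among them. St6gal1 (1.35 ± 0.43 against 1.63 in the whole class, edgeR adjusted p = 0.219) and Fosb (−0.56 ± 0.36, adjusted p = 0.9996) were not called. Neurl3, Spp1, Atf3 and Ccl9 were too low to test. Klk1 stood at 11.6 and 27.3 CPM against 111 (log2 fold change −2.46 ± 0.25, edgeR adjusted p = 4.12e-11). The class also held more transcripts of late neutrophil granules, Mmp8 at 121 and 68.7 CPM against 10.0 (3.21 ± 0.31, edgeR adjusted p = 6.09e-12) and Ly6g with 37 counts against 0 (at least 10.8-fold), with 11 of 17 list members higher (12 adjusted over the list alone, median 1.65, camera adjusted p = 9.55e-16, adjusted p = 0.814 with an estimated correlation). Among the cells named at both resolutions, 3 of 11 members were higher and 2 lower (median 0.88). The rise was not particular to this class. In the larger basophil cluster, 7 of 17 members were higher and 1 lower by edgeR (median 0.996). In granulocyte-monocyte progenitors named at both resolutions the median was 0.66, with 0 of 18 members called. In monocytes without dendritic cells, 1 of 17 members was higher and 4 lower (median −0.63). The same list was lower in T, NK and innate lymphoid cells, the measure of free RNA (9 of 14 members, median −1.50), in stem and multipotent progenitors (9 of 16, median −1.81) and in erythroblasts (9 of 15, median −2.53), with camera adjusted p = 9.18e-14, 5.38e-14 and 1.8e-12. Adjusted over the list alone, 11, 14 and 13 members were lower and 0, 1 and 1 higher in these classes, each with adjusted p = 0.814 with an estimated correlation.

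Basophils of the fusion marrow lost Fcer1a, the alpha chain of the IgE receptor (ENSMUSG00000005339), with Htr1b (a serotonin receptor), Cd7, Ptgs2 (cyclooxygenase-2) and Kcnj2. Higher were Cd34, Meis1, Hoxa7, Il10ra, Slc22a15, Zfhx3 and Cma1 (mast cell chymase, 62.0 and 10.0 CPM against 3.55), while Cpa3 was lower (log2 fold change −0.72 ± 0.22, edgeR adjusted p = 0.0382). With equal cells per library, edgeR called 0 genes in this class against 724 with all cells (1185 at an unadjusted p under 0.05), and Fcer1a stood at −3.86 on the log2 scale (adjusted p = 0.382). DESeq2 called 49 with all cells. Fcer1a stood at 55.5 and 71.4 CPM against 790 (log2 fold change −3.63 ± 0.21, edgeR adjusted p = 5.98e-14), Cd34 at 89.7 and 74.5 against 19.9 (2.03 ± 0.22, adjusted p = 5.31e-08) and Meis1 at 58.7 and 60.1 against 24.3 (1.29 ± 0.21, adjusted p = 9.23e-05). The basophil and mast cell list had 10 of 14 members lower and 1 higher, the same adjusted over the list alone, with Mcpt8, Cyp11a1 and Ccl3 after Fcer1a (median −0.97, camera adjusted p = 5.52e-07, adjusted p = 0.814 with an estimated correlation). The G2 and M phase list had 15 of 34 members lower, Prc1 and Cenpe among them (23 adjusted over the list alone, median −0.63, camera adjusted p = 1.69e-10, adjusted p = 0.814 with an estimated correlation). The larger of the 2 basophil clusters held 117 and 157 fusion cells against 544 of wild type, the smaller 74 and 112 against 58. In the larger cluster alone, edgeR called 251 genes, Fcer1a fell by 2.96 ± 0.24 on the log2 scale, and 2 of 14 basophil genes (median −0.37) and 1 of 34 G2 and M phase genes (median −0.35) were lower.

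Pro-B cells of the fusion marrow expressed Ms4a1 (CD20, ENSMUSG00000024673), a marker of later B cells, and Rag1, which recombines antigen receptor genes. Cd36 (a scavenger receptor), Rnase6, Scd1 and Gbp7 rose as well, while the granule genes Mpo, Elane (neutrophil elastase) and Prtn3 fell, as did Map7, Slc12a3, H2-Aa and Fos. Ms4a1 stood at 93.6 and 83.9 CPM against 2.77 (log2 fold change 4.92 ± 0.49, edgeR adjusted p = 3.2e-20), Rag1 at 261 and 162 against 70.7 (1.55 ± 0.25, adjusted p = 5.86e-07) and Mpo at 30.5 and 26.5 against 284 (−3.33 ± 0.27, adjusted p = 1.21e-29). Mpo fell as well in T, NK and innate lymphoid cells, as given above. The primary granule list had 5 of 12 members lower in pro-B cells, the same adjusted over the list alone (median −1.60, camera adjusted p = 6.2e-13, adjusted p = 0.814 with an estimated correlation). The early B cell list had 1 of 22 members higher, 2 adjusted over the list alone, and did not pass camera (median 0.21, adjusted p = 0.0605). By edgeR, 26 genes were higher and 27 lower. The class held 55 and 74 fusion cells and 151 of wild type, but 144, 153 and 324 at Leiden resolution 2. Its border with later B cells thus moved, and Ms4a1 was at most 5.96% of its highest class CPM. The rise of Ms4a1 is therefore not separated from a different mix of stages.

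Pre-B to mature B cells had less Cr2 (complement receptor 2) and Fcer2a (CD23), which mark mature B cells, and less Ciita, H2-Eb1 and H2-Ab1. Cd36, Rilpl2, Ckap4, Ahnak and Socs2 (a cytokine signalling inhibitor) rose. Fcer2a stood at 37.4 and 46.5 CPM against 171 (log2 fold change −2.02 ± 0.31, edgeR adjusted p = 9.07e-08), and Socs2 had 39 counts against 2, a 19.6-fold ratio (counting interval 5.08 to 168). Lrrk2, 10.1 Mb from Ep300, stood at 6.60 and 15.5 against 70.3 CPM. At Leiden resolution 2, the class went from 167 and 158 fusion cells and 356 of wild type to 78, 79 and 183, while the pro-B class grew. The class spans stages from pre-B to mature B cells, so the changes are not separated from its mix of stages. By edgeR, 21 genes were higher and 43 lower, but 0 were called without the gene filter (415 at an unadjusted p under 0.05), and DESeq2 called 2. The MHC class II list had 3 of 11 lower (6 adjusted over the list alone, median −0.70, camera adjusted p = 2.84e-05, adjusted p = 0.814 with an estimated correlation).

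Among T, NK and innate lymphoid cells, Pdlim4, Ly6c1 (6.54 Mb from Ep300), Dapl1, Cd163l1 and Pik3ip1 rose, and Ncr1 (the NK receptor NKp46), Klra3 (an NK receptor), Ccr10, Stab2 and Mzb1 fell. Ncr1 stood at 13.6 and 12.4 CPM against 137 (log2 fold change −3.38 ± 0.42, edgeR adjusted p = 7.68e-13). Mzb1 had 0 counts in fusion and 80 in wild type and was at least 15.9-fold lower, at 12.7% of its highest class CPM. Jchain (the immunoglobulin joining chain) had 1 count against 201 (ratio 120, counting interval 21.3 to 4757). At Leiden resolution 2, plasma cells made up 0.082% and 0.116% of fusion cells and 0.686% of wild-type cells. The fall of Mzb1 is therefore not separated from plasma cells or their free RNA. The lower plasma cell share did not hold in other settings. With doublets kept it was 0.133% and 0.125% against 0.328%, not apart. With the stricter filter it was 0% and 0.594% against 0.092%. Stab2 had 3 counts against 98 (ratio 19.5, counting interval 6.47 to 96.1) and Klra3 2 against 61 (18.2, 4.82 to 154). By edgeR, 48 genes were higher and 103 lower (75 called in all with equal cells per library), while DESeq2 called 5. G2 and M phase genes such as Aurkb, Prc1, Nusap1 and Cenpe fell (11 of 30 lower, 20 adjusted over the list alone, median −1.13, camera adjusted p = 4.94e-18, adjusted p = 0.814 with an estimated correlation). The class mixes types: a cluster led by Gata3, Rora, Ccr10 and Stab2 held 23 and 12 fusion cells against 76 of wild type, and the other 76 and 62 against 143.

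Interferon-response genes were lower in the fusion libraries in much of the marrow. Rsad2 (viperin), Ifi44, Ifi27l2a and Xaf1 fell in stem and multipotent progenitors, and Ifit3, Zbp1, Ifit2 and Gbp2 in mature neutrophils. Rsad2 stood at 9.43 and 13.2 CPM against 40.4 in stem and multipotent progenitors (log2 fold change −1.82 ± 0.28, edgeR adjusted p = 0.00669), and Ifit3 at 2.45 and 5.36 against 42.1 in mature neutrophils (−3.46 ± 0.32, adjusted p = 5.13e-10). The list passed camera as lower in 10 of 14 classes. Its median was −0.83 in stem and multipotent progenitors (5 of 28 members lower, 19 adjusted over the list alone), −0.79 in erythroid progenitors (7 of 29, 23), −0.93 in immature neutrophils (17 of 26, 21) and −1.11 in mature neutrophils (17 of 27, 22). In these classes camera gave adjusted p = 1.3e-14, 1.27e-12, 2.97e-13 and 9.23e-10, and adjusted p = 0.814 with an estimated correlation in each. The other classes that passed were granulocyte-monocyte progenitors, lymphoid progenitors, erythroblasts, megakaryocytes, monocytes and plasmacytoid dendritic cells, with medians of −0.54, −0.60, −0.84, −0.30, −0.30 and −0.37 and 9, 2, 7, 0, 7 and 1 members lower adjusted over the list alone, each again with adjusted p = 0.814 with an estimated correlation. Among plasmacytoid dendritic cells named at both resolutions, 0 of 16 members were called by edgeR (median −0.12). In the immature neutrophil clusters shared by all libraries, 0 of 21 members were called by edgeR (median −0.43). The list was not called in basophils, pro-B cells, pre-B to mature B cells, or T, NK and innate lymphoid cells.

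**Figure D3:**
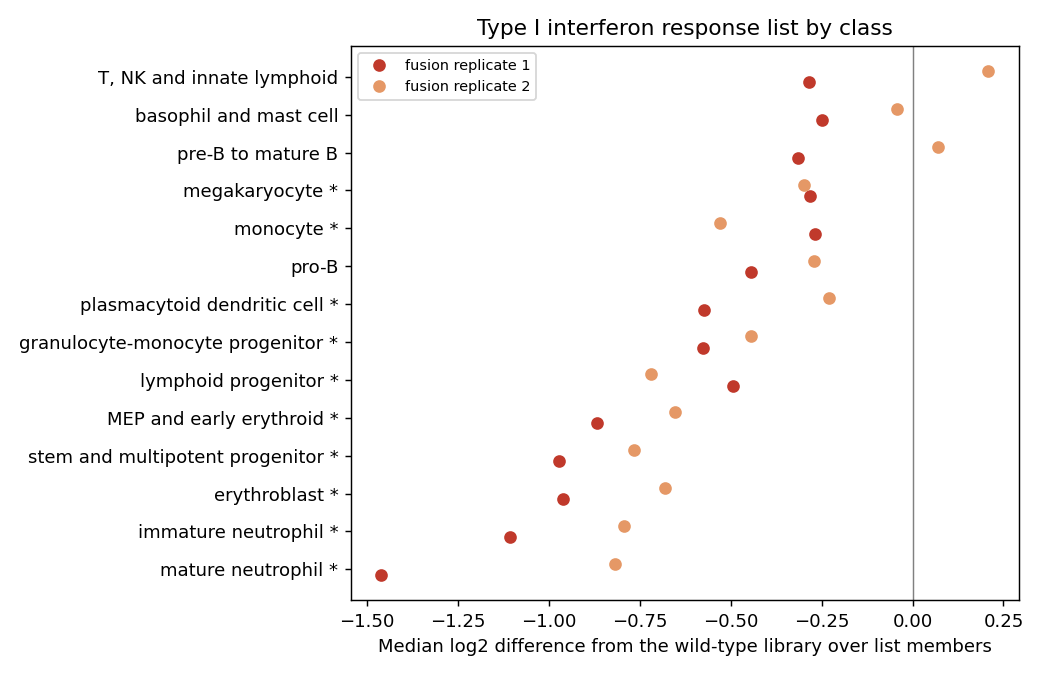
Median log2 fold change of the interferon list in each class, fusion over wild type, with 1 point per fusion replicate, and an asterisk where camera with the preset correlation passed. Medians over both replicates range down to −1.11 in mature neutrophils.

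Of genes reported raised in human leukaemia with ZNF384 rearrangement, a list that includes Cebpa, Cd33 and Flt3, 0 were higher and 2 of 7 lower in immature neutrophils by edgeR (Cebpa −1.49 and Cd33 −0.70 on the log2 scale, 3 adjusted over the list alone, median −0.70). In the immature neutrophil clusters shared by all libraries, 0 of 5 members were called by edgeR (median −0.41). The list passed camera as lower in the whole class (adjusted p = 0.00221) and in erythroid progenitors (median −0.79, 0 of 9 called by edgeR and 3 adjusted over the list alone, adjusted p = 0.00232), and gave adjusted p = 0.814 with an estimated correlation in both. The lists of glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, p53 target and histone acetyltransferase genes did not pass camera in any class.

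Joint detection of granule and early B cell genes was examined because the title names lineage aberrancy. At 2000 UMIs per cell, 26.1% and 30% of fusion stem and multipotent progenitors and 39.9% of wild-type ones had a UMI of both lists. A granule UMI was found in 99.1% and 99.5% of these fusion cells and 100% of the wild-type ones. The joint share therefore equals the share with an early B cell UMI. The joint shares lie below those of T, NK and innate lymphoid cells (70.6% and 69.4% in fusion, 51.2% in wild type), which therefore give no usable background for them. In lymphoid progenitors the shares were 93.4% and 85.3% against 93.9%, and in pro-B cells 94.4% and 91.7% against 89.6%. An early B cell UMI was found in 100% of pro-B cells in every library, so the joint share there is the granule share. In lymphoid progenitors a granule UMI was found in 100% and 97.9% of fusion cells and 98.4% of wild-type cells. With 1 list at or near its ceiling, the measure cannot show joint lineage detection in any of the 3 progenitor classes. The exact permutation test gave p = 0.333, 0.667 and 0.667 for the 3 progenitor classes. Unthinned, the shares were 68.3% and 70.0% against 80.4% in stem and multipotent progenitors and 85.9% and 79.7% against 80.8% in T, NK and innate lymphoid cells. Median depths were 9406 and 11196 UMIs against 10157 in the former and 2875 and 3979 against 4325 in the latter.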

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

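For the 5 gene lists below, the requirement of at least 1 called member per direction was chosen only after the result was seen. Each result is a gene or list that both fusion libraries moved one way in one class and the opposite way in another, and none of these differences was tested. Values are the gap between the classes' log2 fold changes, fusion over wild type, and for lists between their medians.

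The MHC class II list was higher in monocytes and lower in T, NK and innate lymphoid cells (gap 4.15). The early B cell list was higher in T, NK and innate lymphoid cells and lower in immature neutrophils (2.59), and the lymphoid priming list was higher in the former and lower in stem and multipotent progenitors (0.735). Late granule genes were higher in plasmacytoid dendritic cells and lower in erythroblasts (4.18). The unfolded protein response list was higher in immature neutrophils and lower in basophils (0.831), but its median was 0.28 in the immature clusters shared by all libraries and −0.18 in the larger basophil cluster, where 0 of 18 members were called by edgeR.

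Apoe was higher in lymphoid progenitors and lower in pre-B to mature B cells (5.14), and Ciita was higher in monocytes and lower in pre-B to mature B cells (4.45). Cpa3 was higher in stem and multipotent progenitors and lower in basophils (2.28), and Ctsg higher in stem and multipotent progenitors and lower in pro-B cells (4.29). Fabp5 was higher in erythroblasts (4.48), Fam169b in lymphoid progenitors (4.68) and Gbp7 in pro-B cells (4.05), each against a lower value in mature neutrophils. H2-Aa was higher in basophils, with 23 counts against 2 (ratio 11.7, counting interval 2.90 to 103), and lower in T, NK and innate lymphoid cells (fitted gap 6.20, which depends on the prior count). Klf2 was higher in pro-B cells and lower in stem and multipotent progenitors (2.95), and Ms4a1 was higher in pro-B cells and lower in erythroid progenitors (7.63). Zfhx3 was higher in basophils and lower in immature neutrophils (4.24).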

How the results depend on the processing

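Chosen only after the result was seen were the tests named as added here and every value for stem joined with lymphoid progenitors, and all others were set beforehand. Shares are fusion over wild type ratios, read as moved where they shifted by more than 1 SD of the 2 fusion ratios. Over the alternatives run, lymphoid progenitors stayed between 0.223 and 0.322, erythroid progenitors between 2.05 and 2.26, and T, NK and innate lymphoid cells between 0.364 and 0.514. A separate lymphoid progenitor class did not form at resolution 0.5, with wild-type classes, with doublets kept or when clustered without called genes, and the stem ratio turned in these 4 settings. At resolution 0.5 and without called genes, the stem class held 515 and 535 wild-type cells against 534 in stem and lymphoid progenitors joined, with ratios near the joined 0.616, so there the turn goes with the joining of the classes. With doublets kept, the class held 755 wild-type cells and was wider than both. For this and all other changes below, the cause was not tested. Leaving out a fusion replicate gives values without a test, since no residual degree of freedom is left: ratios ran from 0.247 to 0.268 for lymphoid progenitors, 2.14 to 2.22 for erythroid progenitors and 0.322 to 0.482 for basophils. No paired analysis was possible because the wild type has 1 library and replicate numbers follow only the order of deposit. In simulated counts, 9.68% of genes changed 2-fold were recovered in pro-B cells and 84.2% of those changed 4-fold. Even under the assumptions of that simulation, most small changes there would be missed.

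At resolution 0.5, the ratios were 1.46 for immature neutrophils (turned), 1.01 for mature neutrophils, 1.66 for megakaryocytes and 0.620 for the stem class (turned). At resolution 2, they were 1.49 for immature neutrophils (turned), 1.01 for mature neutrophils, 2.14 for megakaryocytes, 0.536 for monocytes, 0.406 for plasmacytoid dendritic cells, 0.449 for pre-B to mature B cells and 1.63 for the stem class. With wild-type classes, they were 1.9996 for erythroblasts, 1.22 for immature neutrophils (turned), 1.11 for mature neutrophils, 0.391 for plasmacytoid dendritic cells, 0.482 for pre-B to mature B cells, and 0.542 for the stem class (turned) and for stem joined with lymphoid progenitors. With doublets kept, they were 1.97 for erythroblasts, 0.871 for immature neutrophils, 0.441 for plasmacytoid dendritic cells, 0.464 for pre-B to mature B cells, and 0.966 for the stem class (turned) and the joined class. Clustered without called genes (added), they were 1.89 for erythroblasts, 1.03 for immature neutrophils, 1.70 for megakaryocytes, 0.468 for pre-B to mature B cells, 0.458 for pro-B cells (no longer apart) and 0.639 for the stem class (turned). With the stricter filter, they were 0.890 for immature neutrophils, 0.223 for lymphoid progenitors, 2.26 for erythroid progenitors, 0.351 for plasmacytoid dendritic cells, 0.475 for pre-B to mature B cells and 0.579 for the joined class. Within a compartment, they were 0.242 for lymphoid progenitors, 1.73 for megakaryocytes, 2.05 for erythroid progenitors, 0.492 for pre-B to mature B cells, 1.45 for the stem class, 0.577 for the joined class and 1.99 for all erythroid cells.

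Outside the erythroid classes (added), ratios rise by construction: 0.514 for T, NK and innate lymphoid cells, 0.742 for granulocyte-monocyte progenitors, 1.20 for immature neutrophils (turned), 0.322 for lymphoid progenitors, 1.68 for mature neutrophils, 2.30 for megakaryocytes, 0.826 for monocytes (no longer apart), 0.663 for plasmacytoid dendritic cells, 0.597 for pre-B to mature B cells, 0.563 for pro-B cells, 1.94 for stem and multipotent progenitors, 1.45 for all neutrophils, 0.770 for the joined class and 0.587 for all B cells. The edgeR test of class counts did not pass granulocyte-monocyte progenitors (0.592), mature neutrophils (1.35), monocytes (0.660) or stem and multipotent progenitors (1.55).

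Counts of called genes depended on the tool. DESeq2 called 5 in T, NK and innate lymphoid cells, 1275 in all cells, 49 in basophils, 13 in erythroblasts, 36 in granulocyte-monocyte progenitors, 121 in immature neutrophils, 6 in lymphoid progenitors, 243 in mature neutrophils, 1 in megakaryocytes, 83 in erythroid progenitors, 36 in monocytes, 12 in plasmacytoid dendritic cells, 2 in pre-B to mature B cells, 7 in pro-B cells and 7 in stem and multipotent progenitors. With equal cells per library, edgeR called 75 in T, NK and innate lymphoid cells, 0 in basophils (1185 at an unadjusted p under 0.05, against 724 called with all cells, DESeq2 not run on that draw), 66 in erythroblasts, 5 in granulocyte-monocyte progenitors, 6 in lymphoid progenitors, 102 in megakaryocytes, 53 in plasmacytoid dendritic cells, 36 in pre-B to mature B cells and 18 in stem and multipotent progenitors. DESeq2 size factors gave 64 in erythroblasts, 45 in lymphoid progenitors and 62 in megakaryocytes. Without a gene filter, edgeR called 184 in erythroblasts, 383 in granulocyte-monocyte progenitors, 113 in lymphoid progenitors, 147 in megakaryocytes, 0 in erythroid progenitors (934 at an unadjusted p under 0.05), 295 in monocytes, 0 in pre-B to mature B cells (415) and 116 in stem and multipotent progenitors. Wild-type classes gave 240 in basophils, 11 in granulocyte-monocyte progenitors, 311 in immature neutrophils, 63 in megakaryocytes, 30 in erythroid progenitors, 39 in monocytes and 406 in stem and multipotent progenitors. The last of these is not the same class, since no separate lymphoid progenitor class formed there. The larger basophil cluster gave 251, the shared immature neutrophil clusters 108, and the plasmacytoid dendritic cells and granulocyte-monocyte progenitors named at both resolutions 23 and 5 (all added). Of 145 class and gene pairs that the naming rule gave, 71 kept their side of the threshold with DESeq2, 67 lost their call and 7 gained one, and 141 kept it with DESeq2 size factors. None of these genes turned in sign under the alternatives run. For leaving out a fusion library this was fixed in advance, since the rule took only genes with both fusion libraries on one side. The other alternatives reuse much the same counts for genes picked by large changes, so the unchanged signs say little.

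Of the list calls (26 higher and 116 lower), 0 held with an estimated correlation (smallest adjusted p = 0.814), 0 with fry's directional test (0.371) and 0 with its mixed test (0.0848). With 1 residual degree of freedom, the test with an estimated correlation could hardly pass. Thinned to 1000 UMIs, joint detection differed by −5.40 points in stem and multipotent progenitors and −10.8 in lymphoid progenitors, and unthinned by 0.402 in pro-B cells.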

Other observations

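The tests of the pooling, of erythroid cells taking up room, of clusters drawn by changed genes, of higher and lower neutrophil genes apart, and of interferon genes in T, NK and innate lymphoid cells and the other classes without a call were chosen only after the result was seen.

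The MHC class I presentation list passed camera as lower in stem and multipotent, lymphoid, granulocyte-monocyte and erythroid progenitors, immature and mature neutrophils and plasmacytoid dendritic cells, each with adjusted p = 0.814 or above with an estimated correlation. By edgeR, 0 of 15 members were called in the immature neutrophil clusters shared by all libraries (median −0.30) and 0 of 15 in the plasmacytoid dendritic cells named at both resolutions (median −0.12). In mature neutrophils 3 of 15 list members were lower by edgeR over all genes and 5 adjusted over the list alone (median log2 fold change −0.37, camera adjusted p = 0.00384, adjusted p = 0.814 with an estimated correlation). In erythroid progenitors 2 of 16 were lower, the same adjusted over the list alone (median −0.25, camera adjusted p = 0.000148, adjusted p = 0.814 with an estimated correlation). S phase genes such as Rrm2, Hells and Rrm1 were lower in T, NK and innate lymphoid cells (3 of 27 by edgeR, 6 adjusted over the list alone, median −0.67, camera adjusted p = 3.28e-10, adjusted p = 0.814 with an estimated correlation).

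A larger share of erythroid and a smaller share of lymphoid cells were seen in both fusion libraries. Unequal pooling of bulk and lineage-negative cells would leave shares among progenitors level, yet the erythroid progenitor share among progenitor classes was at least 1.98 times the wild type in each fusion library. Room taken up by erythroid cells would leave the lymphoid progenitor share of the other cells level, yet it was at most 0.339 of the wild type. Clustered without the called genes, the erythroid progenitor share was still at least 2.14 times the wild type. A difference between animals, or in the yield of the sort, was not tested and stays open beside the genotype, since 1 wild-type library was analysed.

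The genes called in mature neutrophils may come from a different mix of maturation stages within the class. If so, their fusion levels should lie within the range of 5 wild-type neutrophil stages, and 14.8% of the 795 genes lay more than 1.5-fold outside it, between the bounds set beforehand. Of the genes called higher, 33.9% (108 of 319) lay above every stage, which argues against stage mix as the whole cause of these. Of 130 genes called lower with at least 20 CPM in every stage, 5.38% (7) lay below every stage, near the lower bound, so stage mix stays open for these. Within 20 Mb of Ep300 lay 2.52% of called genes and 2.52% of tested genes. Passenger variants that act on the genes beside them are therefore argued against as the cause of the pattern. Over all classes, 16.5% of genes near Ep300 and 13.8% of the others were called (Fisher exact p = 0.143). A passenger variant that changes genes elsewhere would not raise these shares, so it stays open.

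The lower interferon list may reflect free RNA, a strain difference, a state of the wild-type library or the genotype. Free RNA from a single source should add a like number of UMIs to each cell. At the wild-type depth, the difference between wild type and fusion ranged from 3.17 to 13.7 UMIs per cell over the 10 classes called, a 4.31-fold range between the bounds set beforehand. At each library's own depth the spread was wider. For fusion replicates 1 and 2 it was 18.8 and 10.5 UMIs per cell in monocytes. In plasmacytoid dendritic cells it was −0.17 and −1.82, the only called class with negative values. In T, NK and innate lymphoid cells, the measure of free RNA, the difference was −1.14 UMIs per cell at the wild-type depth, but 2.66 and −0.49 for the 2 fusion libraries at their own depths, so free RNA stays open, and tests on basophils (−0.518) and on the 4 classes not called (0.0909 at most) decide nothing, since these were picked for lacking the change. The 22 members called in any class lay on 12 chromosomes, with at most 13.6% on any of them. This argues only against a single strain region that holds the changed genes themselves. A linked variant that changes genes elsewhere would give the same spread, so it stays open, as do unlinked strain differences. With 1 wild-type library, a state of that animal or library and an effect of the genotype cannot be told apart.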
